A study of Mus musculus with 6 samples.

How the data were processed

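RNA from 6 cell samples, 3 groups of 2, was hybridized to Affymetrix mouse gene arrays (MoGene 1.0 ST), 1 sample per array. RNA was taken with a silica column kit and amplified and biotin-labelled with the Ambion WT and Affymetrix kits, per the labels' protocols. The deposited values are log2 RMA signals per gene-level probe set, made with Affymetrix Expression Console, per the submitters' processing notes and the file headers. RMA corrects background, quantile-normalizes the arrays and summarises probes, so a change shared by most genes of an array would be removed. Software version, annotation release and genome build are not given in the sources used here. The authors also deposited log2 differences of group means and linear fold values (the ratio, 2 to the power of those differences), per the file headers. An annotated table and a series table were given, and their signals were equal at every probe set to 6 decimals, so the series table as an alternative changes nothing by construction.

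The annotated table names 18087 gene symbols and left 0 probe sets without a symbol, so testing all rows is the same as the main setting. Of the symbols, 15578 were current in the GRCm38.p6 gene table, 2073 matched through a synonym and 436 did not match. Symbols are printed as the file gives them. A chromosome position was given for 19609 probe sets. On 9 of 21 chromosomes a probe set ended beyond the last gene of GRCm38.p6, so no coordinates of that assembly were used. For 347 probe sets all 6 values equal those of another probe set, so genes they share cannot be told apart. The table held no annotation terms, and the planned term enrichment was not run.

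Tested were probe sets at a log2 signal of 6 or more on at least 2 arrays, 10468 in all, and 10141 were below this level. A linear model with a mean per group was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 3 residual and 2.3 prior degrees of freedom. The 3 two-sided contrasts were PAX2 over vector, PAX2+Cre over PAX2 and PAX2+Cre over vector. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. All adjusted p-values of genes come from limma. Differences are log2, first group minus second, with their standard error.

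Gene lists were fixed before the data were examined, 32 in all, of which 25 had at least 5 measured members. Measured means past the level filter, so members below it are not counted. Each gene was represented by its probe set of highest mean. Lists, and the genes of each chromosome, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Also run was fry, which compares a list's members between groups without reference to other genes. P-values were adjusted by Benjamini-Hochberg over lists or chromosomes within a comparison. Where no test is named, those of sets are from camera. A camera call can be lost with an estimated correlation although that correlation lies below 0.01. Such a loss need not reflect correlated members. Lists share members and are not independent. Genes were named by a rule fixed before the data were examined: Pax2, the 10 largest rises and 10 largest falls among calls whose groups did not overlap (5 and 5 for PAX2+Cre over vector), and up to 4 members of each list, those called with the largest difference or else those of smallest p. Predicted genes, clones and receptor families were passed over. Lgr5, Ccnd1, Bnip3, Id2, Gata3 and Fos in PAX2+Cre over PAX2 came under the list part of the rule.

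The procedure was tested on simulated data with the real means and the unequal spreads of the groups, with 100 probe sets changed by 1 and 100 by 2 log2 units among 10468. For PAX2 over vector it recovered 63% of the former and 91% of the latter, and called 39 of 9987 unchanged probe sets. For PAX2+Cre over PAX2 it recovered 68% and 96% and called 18 unchanged, and for PAX2+Cre over vector 58% and 89% with 5. A shift of 0.5 added to chromosome 16 was called in each, with 0 other chromosomes. Noise was drawn independently for each probe set. The simulation therefore does not show how often correlated genes give false calls of chromosomes or lists.

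Alternatives fixed beforehand were other level filters, another quantile normalization, median centring, a trended and robust variance, a fit of only the 2 groups compared, the replicate number as a block, averaging of a gene's probe sets, other thresholds and leaving out each array. Chosen after the data were seen were the mean of the arrays labelled PAX2+Cre as 1 sample, array weights estimated by group, and removal of each array's median deviation per chromosome.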

Results

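Gene expression was measured in a mouse ovarian surface epithelial cell line, M0505, of FVB/N background. Ovarian surface epithelium is the cell layer that covers the ovary. The line carried a GFP lentiviral vector (vector line, 2 arrays) or a construct expressing PAX2 and GFP (PAX2 line, 2 arrays), each sorted for GFP. PAX2 is a paired-box transcription factor of the developing kidney and Müllerian duct. The remaining 2 arrays were labelled PAX2+Cre, a subline of the PAX2 line exposed to adenoviral Cre recombinase to delete PAX2 and GFP and sorted for the loss of GFP. The labels call the 2 arrays of each group biological replicates, with nothing on separate cultures. P-values measure the spread between the 2 arrays of a group, pooled over the 3 groups, also where only PAX2 and vector are compared. The median SD between the 2 arrays was 0.127 in vector, 0.173 in PAX2 and 0.033 for those labelled PAX2+Cre. The last pair therefore lowers the pooled spread. Each array gave log2 RMA signals for probe sets of 18087 gene symbols, with array medians between 5.85 and 5.89, and 10468 probe sets of 9194 genes passed the level filter. The number of arrays, 2 per group, limits the precision of every value.

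Pax2 itself was examined first, because it checks the labels. Its probe set lies on chromosome 19 from 44831883 to 44910517 in the deposited annotation, whose genome build is not given in the sources used here. The Pax2 signal was 8.36 and 6.37 on the vector arrays, 11.35 and 11.29 on the PAX2 arrays, and 10.990 and 11.004 on the arrays labelled PAX2+Cre. PAX2 exceeded vector by 3.96 log2 units (SE 0.62, adjusted p = 0.0244), a 15.5-fold difference. The arrays labelled PAX2+Cre lay 3.63 above vector (SE 0.62, adjusted p = 0.0349). Against the PAX2 arrays they lay at -0.32 (SE 0.62, adjusted p = 0.888). The difference of PAX2 from vector was 4.95 without vector replicate 1 and 2.96 without vector replicate 2, and it was no longer called without either PAX2 array or either array labelled PAX2+Cre (3.93 to 3.98). That of the arrays labelled PAX2+Cre from vector was no longer called without either of them (3.64 and 3.63). The target gene therefore went against the label of the PAX2+Cre arrays, and each direction given for those arrays below is that of arrays that still carried a high Pax2 signal. Which part of the transcript the probes read, and the species of the construct's PAX2, are not given in the sources used here.

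The replicate pairs were unequally close. The 2 arrays labelled PAX2+Cre differed by an SD of 0.077 log2 units over the tested probe sets, with 0 probe sets apart by more than 2-fold. The vector arrays differed by an SD of 0.406 with 321 such probe sets, and the PAX2 arrays by 0.487 with 514. The noise of a repeated hybridization was not measured in this series, so the PAX2+Cre arrays were kept as 2 samples, and counts are also given with their mean as 1 sample. The first principal component held 57.3% of the variance and placed the vector arrays at -37.9 and -37.7, the PAX2 arrays at 22.4 and 22.2, and the arrays labelled PAX2+Cre at 15.7 and 15.4. On the second, with 23.6%, PAX2 replicate 1 stood at 35.2, PAX2 replicate 2 at -9.91 and the arrays labelled PAX2+Cre at -14.4 and -14.1. PAX2 replicate 2 differed from the arrays labelled PAX2+Cre by SDs of 0.300 and 0.290, with 105 and 106 probe sets apart by more than 2-fold. For PAX2 replicate 1 these were 0.499 and 0.496, with 537 and 517. PAX2 replicate 2 was thus closer to the arrays labelled PAX2+Cre than to PAX2 replicate 1.

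The first comparison asked what differed between the PAX2 line and the vector line. The largest rises were in Itm2a, which encodes an integral membrane protein (5.12, SE 0.53, adjusted p = 0.0102), Igfbp5, an insulin-like growth factor binding protein (4.84, SE 0.27, adjusted p = 0.00281), and Sorbs2 (4.40, SE 0.61, adjusted p = 0.0185). Gprc5c, the inflammatory caspase Casp1, Raver2, the matrix glycoprotein Tnc, Sema5a and the R-spondin receptor Lgr5 rose by 4.38, 4.21, 4.17, 4.13, 3.94 and 3.75 log2 units. The largest falls were in Ankrd1, which encodes an ankyrin repeat protein (-4.61, SE 0.13, adjusted p = 0.00164), Pdlim1 (-4.51, SE 0.37, adjusted p = 0.00677) and Perp, a desmosomal protein and p53 target (-4.45, SE 0.26, adjusted p = 0.00281). Ccnd1, the cyclin D1 gene, Cyp4f39, Serpinb9b, Prrg4, Crct1, the glutathione transferase gene Gsta3 and Zc3hav1 fell as well, with differences of -3.78, -3.64, -3.55, -3.50, -3.50, -3.45 and -3.41. Mean Tnc signal was 10.31 ± 0.014 in PAX2 and 6.19 ± 0.51 in vector (SD, n = 2), and mean Perp signal was 4.25 ± 0.53 and 8.70 ± 0.14 (SD, n = 2). For most of these genes the mean of the lower group lay under the level of 6, as for Itm2a (3.81), Igfbp5 (5.57), Sorbs2 (4.03) and Casp1 (3.45) in vector and Ankrd1 (4.63) and Pdlim1 (5.37) in PAX2. Signal against background was not given for these arrays, so the exact size and rank of such differences are uncertain, here and in the comparisons below.

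In all, 1017 of 10468 probe sets passed an adjusted p of 0.05, 525 higher and 492 lower in PAX2, and 463 of them differed by at least 2-fold. With the arrays labelled PAX2+Cre counted as 1 sample, 146 were called, 65 higher and 81 lower. Of the 72 named genes called here besides Pax2, 25 stayed called then, among them Itm2a, Igfbp5, Casp1, Tnc, Lgr5, Ankrd1, Perp and Ccnd1. Sorbs2, Gprc5c and Gsta3 were no longer called, and neither was Pax2 (adjusted p = 0.0794). The count was 591 without vector replicate 1, 584 without vector replicate 2, 1996 without PAX2 replicate 1, 1652 without PAX2 replicate 2 and 146 without either array labelled PAX2+Cre.

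**Figure D1:**
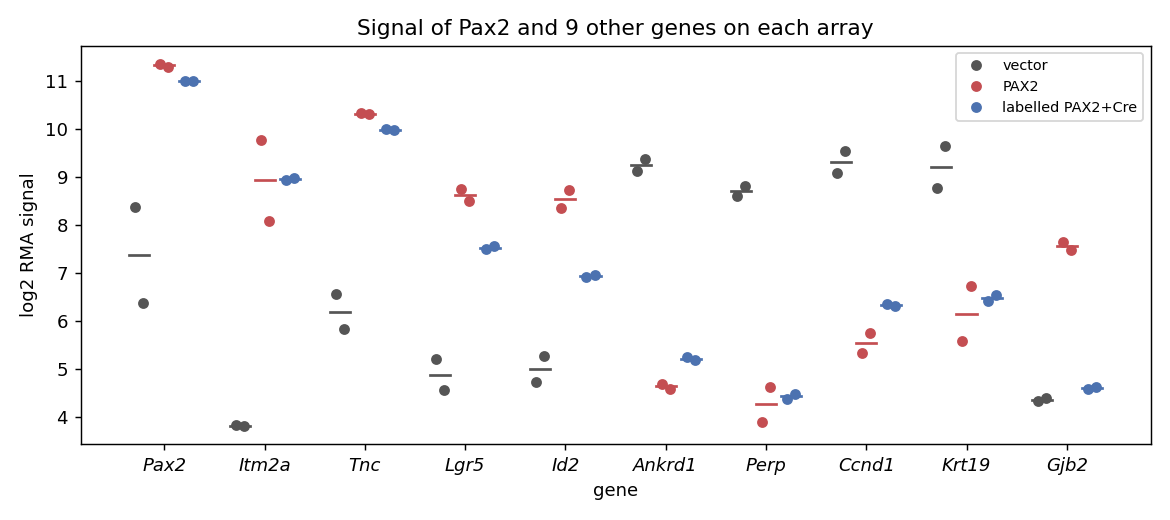
Log2 RMA signal (vertical axis) of Pax2 and 9 other genes (horizontal axis) on each of the 6 arrays, coloured by group, with a line at each group mean. The arrays labelled PAX2+Cre sit at 10.990 and 11.004 for Pax2, near the PAX2 arrays at 11.35 and 11.29, while for Gjb2 they lie 2.96 log2 units below the PAX2 mean.

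Genes of the ovarian surface epithelium moved in opposite directions between the PAX2 and vector lines. Of 19 measured members of this list, Lgr5 rose and 3 fell: Krt19, a keratin of simple epithelia (-3.06), the complement gene C3 (-2.68) and the mesothelial surface gene Msln (-1.50). Adjusted over the list alone, 1 rose and 5 fell, and the list as a set did not pass (adjusted p = 0.119). Of 29 epithelial junction and identity genes on the list, 9 were measured. Of these, 1 was called lower (Krt19), 0 higher and 8 neither, with 6 lower when adjusted over the list alone. That list was lower as a set by camera (adjusted p = 0.0109), and fry gave adjusted p = 0.0384. The camera call was lost with an estimated correlation (adjusted p = 0.836), although that correlation, at -0.068, lay below the preset 0.01. The call was also lost without PAX2 replicate 1 (mean -0.74 against -0.92) and with no level filter (mean -0.32). Of 15 mesenchymal genes, the cadherin gene Cdh11 rose by 0.91 and the collagen gene Col3a1 fell by 0.79, and the set did not pass (adjusted p = 0.923). The kidney PAX2 network list had 9 measured genes of 27. Among them Spry1, a feedback inhibitor of growth factor signalling, rose by 2.37. Eya1 (-2.96) and Gata3 (-1.82), both needed for kidney development, fell (adjusted p of the set = 0.923).

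Signalling and matrix genes changed in both directions. Of 17 TGF-beta and BMP targets, 3 rose and 0 fell: Id2, an inhibitor of DNA binding induced by BMP (3.53), the ligand gene Tgfb2 (2.20) and Ltbp1, a binding protein of latent TGF-beta (1.66). This set was higher by camera (adjusted p = 0.0351), and fry gave adjusted p = 0.0384. The camera call was lost with an estimated correlation (adjusted p = 0.836), although that correlation, at -0.031, lay below the preset 0.01. The call, at a mean of 0.63, was also lost without vector replicate 2 (0.51), PAX2 replicate 1 (0.73) or PAX2 replicate 2 (0.52), and with no level filter (0.45) or one at log2 7 (0.628). Of 22 collagen, laminin and matrix genes, 2 rose and 3 fell, including Bgn (2.46), Fbln2 (-2.88) and Fbln5 (-1.79). Of 11 stem and progenitor markers, Lgr5, Sox9 (1.21) and Bmi1 (0.48) rose and Thy1 (-2.62) fell. Among 17 angiogenesis genes the Notch ligand gene Jag1 (1.58) and Pdgfc (0.60) rose, and Pdgfb (-1.70) and Vegfa (-0.68) fell. Of 14 integrin and adhesion genes, L1cam (2.46) and Itgb5 (1.53) rose, and of 15 Wnt pathway genes Lgr5 rose while Ccnd1 and Wnt4 (-0.77) fell. The matrix, stem, angiogenesis, integrin and Wnt sets did not pass (adjusted p = 0.11, 0.805, 0.381, 0.919 and 0.919 in that order).

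Growth and metabolic lists differed as follows. Of 30 cell cycle genes, 2 rose, Gins2 (1.11) and Mcm6 (0.79), both of the replication machinery, and 0 fell, with 27 of 30 differences above 0. The set was higher (adjusted p = 0.00591), which was lost at adjusted p = 0.947 with an estimated correlation. The median of these genes relative to the vector mean was 0.014 on PAX2 replicate 1 and 0.929 on PAX2 replicate 2. Their mean of 0.45 became 0.89 without PAX2 replicate 1 and 0.0044 without PAX2 replicate 2, which ended the call, as did leaving out vector replicate 2 (0.42). Of 20 cholesterol synthesis genes, 3 rose, among them Fdft1 (1.01) and Stard4 (0.63), and 0 fell; the set was higher (adjusted p = 0.0133), with adjusted p = 0.836 with an estimated correlation. The median of this set relative to vector was 0.12 on PAX2 replicate 1 and 0.45 on PAX2 replicate 2, and its mean of 0.34 became 0.55 without PAX2 replicate 1 and 0.12, no longer called, without PAX2 replicate 2. Of 17 p53 targets, Perp and Ccng1 (-0.60) fell and Sesn1 (1.505) rose; the set was lower (adjusted p = 0.0133), with adjusted p = 0.836 with an estimated correlation, and its mean of -0.49 was no longer called without vector replicate 2 (-0.33) or PAX2 replicate 1 (-0.39). Of 14 ATF4 and unfolded protein response genes, Psat1, an enzyme of serine synthesis, fell by 3.09, and the set was lower (adjusted p = 0.0351), with adjusted p = 0.947 with an estimated correlation. Its mean of -0.69 became -0.35 without PAX2 replicate 1, -0.39 without vector replicate 2 and -0.45 with a level filter at log2 7, each of which ended the call. Of 18 hypoxia and glycolysis genes, 5 fell, among them Bnip3 (-2.43) and Egln3 (-2.25), and Ndrg1 (1.02) rose. Of 20 NRF2 and glutathione genes, Gsta3 and the heme oxygenase gene Hmox1 (-1.40) fell, and Gstm1 (2.74) and Gstm3 (1.57) rose. Neither of these last sets passed by camera (adjusted p = 0.328 and 0.312). By fry the hypoxia and glycolysis set passed (adjusted p = 0.00298) and the NRF2 and glutathione set did not (adjusted p = 0.435).

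Of 31 replication histone genes, 7 rose and 0 fell, among them Hist1h1a (2.12), Hist2h4 (0.98), Hist3h2ba (0.89) and Hist2h3b (0.86). The set was higher (adjusted p = 0.00318), which was lost at adjusted p = 0.836 with an estimated correlation. Of the 31 genes, 28 lie on chromosomes 3, 13, 16, 18 or 19, whose medians shifted as described below. With each array's chromosome medians removed, the mean of the set was 0.54 against 0.38, 18 genes were called higher and the set stayed higher (adjusted p = 6.90e-09, and adjusted p = 0.138 with an estimated correlation). The chromosome 13 shift among those removed rests on PAX2 replicate 1, as given below. Without vector replicate 2 (mean 0.27) or PAX2 replicate 2 (0.16) the set was no longer called, and without PAX2 replicate 1 the mean was 0.59. Replication histone transcripts mostly lack poly(A) tails. Of 16 Hox genes, Hoxc12 (-1.68), Hoxb3 (-1.08) and Hoxb5 (-0.93) fell and 0 rose (adjusted p of the set = 0.135). Among 6 prostaglandin genes Cbr1 rose by 1.48 and Ptgds fell by 0.87, and among 7 cytokine and NF-kB genes Birc3 rose by 0.72. Spry1 alone was called among 18 MAPK feedback and immediate early genes. Rpl24 (0.57) was the sole call among 40 ribosomal protein genes and Atp5o (1.58) among 26 respiratory chain genes, and both lie on chromosome 16. With each array's chromosome medians removed, Rpl24 lay at -0.12. None of 11 interferon response genes or 11 matrix protease genes was called by limma over all genes tested. Gbp2 stood at 2.38 (SE 0.69, adjusted p = 0.0951) and Plau at -2.53 (SE 0.69, adjusted p = 0.0838). The sets named in this paragraph after the Hox genes did not pass (adjusted p between 0.0769 and 0.923), while with chromosome medians removed matrix protease genes were lower (mean -0.67, adjusted p = 0.0459, and adjusted p = 0.52 with an estimated correlation).

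Too few members of 7 lists were measured for a set test. Of 22 genes on the oviduct list 4 were measured, that is past the level filter, and Wnt4 fell. Of 23 on the ciliated cell list 2 were measured and neither was called. Among markers of other cells, 3 granulosa genes were measured with 0 calls. The steroidogenic list had 2 measured genes, of which the lipoprotein receptor gene Scarb1 rose by 1.72. The leukocyte list had 2, of which Cd14 fell by 1.45. The stroma list had 2, of which Thy1 fell, and 0 endothelial genes reached the level.

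Genes of some chromosomes differed together between the PAX2 and vector lines. The median log2 difference was 0.68 over 281 genes of chromosome 16, of which 92.9% lay above 0, and 137 genes were called higher and 0 lower. Among the called were Atp5o, Cbr1 and Itgb5. On chromosome 3 the median was 0.43, with 86 genes higher, among them Spry1, Gstm1 and Hist2h4, and 8 lower. On chromosome 18 it was -0.35, with 6 genes higher and 45 lower, among them Cd14. Medians of chromosomes 13 and 19 were -0.28 and -0.16, and single arrays decided both. Chromosome 13 stood at -0.048, no longer called, without PAX2 replicate 1 and at -0.54 without PAX2 replicate 2. Chromosome 19 stood at -0.017, no longer called, without vector replicate 2 and at -0.26 without vector replicate 1. The median of chromosome 3 was 0.28, still called, without vector replicate 2, and chromosome 10 was called in that setting alone among those that leave out an array (median 0.22). With no level filter the medians of chromosomes 16, 3, 18, 13 and 19 were 0.24, 0.17, -0.16, -0.090 and -0.037, all still called. With the filter and all arrays these 5 chromosomes were called by camera (adjusted p = 3.85e-33 for chromosome 16, 2.05e-14 for 3, 1.05e-11 for 18, 6.14e-07 for 13 and 0.000362 for 19). With an estimated correlation, chromosomes 16 (adjusted p = 0.00661) and 18 (adjusted p = 0.0342) remained, and chromosomes 3, 13 and 19 did not (adjusted p = 0.79, 0.791 and 0.791 with an estimated correlation). Of 942 genes called, 355 (37.7%) lay on these 5 chromosomes, which hold 17.8% of the genes tested. The 5 were picked by their shift in this comparison, so an excess of calls there is built in. Chromosome 13 had 9 genes called higher and 28 lower of 346, and chromosome 19 had 5 and 31 of 338. With each array's chromosome medians removed, 775 probe sets were called, 339 higher and 436 lower, so the split turned towards lower calls, and 672 of them were shared with the 1017. Named genes no longer called with these medians removed were Cdh11, Pdgfc, Fbln5, Itgb5, Gstm3, Hoxc12, Hist2h4, Hist2h3b and Rpl24, which also changed sign.

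**Figure D2:**
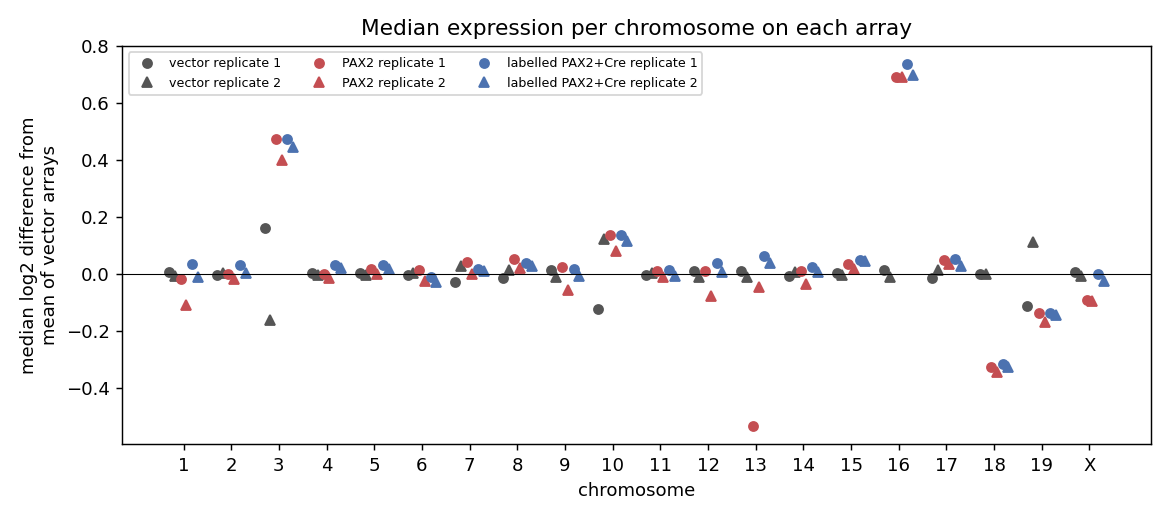
Median log2 difference from the mean of the vector arrays (vertical axis) over the tested genes of each chromosome (horizontal axis), with a point for each of the 6 arrays. On chromosome 16 the PAX2 arrays lie at 0.69 and 0.69 and the arrays labelled PAX2+Cre at 0.74 and 0.70, and on chromosome 13 PAX2 replicate 1 lies at -0.54.

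The second comparison set the arrays labelled PAX2+Cre against the PAX2 arrays, to follow what changed with the deletion of PAX2, although the Pax2 signal stayed high. The gap junction gene Gjb2 fell by 2.96 log2 units (SE 0.11, adjusted p = 0.00749), from 7.56 ± 0.12 to 4.60 ± 0.028 (SD, n = 2), and vector stood at 4.35 ± 0.047 (SD, n = 2). It was the sole call of limma among 10468 probe sets, while 1002 lay under an unadjusted p of 0.05, 669 higher and 333 lower, against 523 expected by chance. Among genes not called, Bnip3 stood at 1.18 (adjusted p = 0.249), Gata3 at 1.03 (adjusted p = 0.277), Id2 at -1.60 (adjusted p = 0.277), Lgr5 at -1.10 (adjusted p = 0.349), Ccnd1 at 0.79 (adjusted p = 0.433) and the immediate early gene Fos at -1.98 (adjusted p = 0.331). With the arrays labelled PAX2+Cre counted as 1 sample, 0 probe sets were called and 224 lay under an unadjusted p of 0.05, fewer than the 523 expected by chance. Without PAX2 replicate 2 there were 682 calls, 411 higher and 271 lower, and without any other array 0 calls.

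Among the lists, p53 targets were higher as a set on the arrays labelled PAX2+Cre than on the PAX2 arrays. Of 17 members, 0 were called over all genes and 6 were higher when adjusted over the list alone, with 15 of 17 differences above 0 (adjusted p of the set = 1.95e-05, and adjusted p = 0.819 with an estimated correlation). Zmat3 stood at 1.00 and Mdm2, which encodes the ubiquitin ligase of p53, at 0.74. Of 20 cholesterol synthesis genes, 0 were called either way and 18 lay above 0, with Cyp51 at 0.81 and Sc5d at 0.70 (adjusted p of the set = 0.000677, and adjusted p = 0.819 with an estimated correlation). Of 11 matrix protease and inhibitor genes, 0 were called over all genes and 1 adjusted over the list alone, with Timp1 at 0.91 and Mmp11 at 0.54 (adjusted p of the set = 0.0268, and adjusted p = 0.819 with an estimated correlation). The cholesterol mean of 0.39 became 0.17 without PAX2 replicate 1, which ended the call, and 0.60 without PAX2 replicate 2. The matrix protease mean of 0.63 became 0.26 and 0.99 in these settings, still called, and the call ended without either vector array and with only the 2 groups compared (0.63 in each). None of the other 22 lists passed by camera, and by fry none of the 25 lists did (smallest adjusted p = 0.26). Replication histones, at a mean of -0.087 (adjusted p = 0.181), were lower with chromosome medians removed (mean -0.36, adjusted p = 1.79e-10, and adjusted p = 0.109 with an estimated correlation). Chromosome 13 was higher by a median of 0.33 (adjusted p = 3.84e-13), a call lost at adjusted p = 0.704 with an estimated correlation, and no longer called without PAX2 replicate 1 (0.067), with 0.59 without PAX2 replicate 2 and 0.11 with no level filter, both called. The chromosome 13 median relative to vector was -0.54 on PAX2 replicate 1, -0.048 on PAX2 replicate 2, and 0.062 and 0.037 on the arrays labelled PAX2+Cre. Chromosomes 16 and 18 had medians of 0.024 and 0.016.

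The third comparison set the arrays labelled PAX2+Cre against the vector arrays, to show what remained after the deletion, and again the Pax2 signal was high on the former. Itm2a (5.14, SE 0.53, adjusted p = 0.012), Casp1 (4.53, SE 0.40, adjusted p = 0.00894), Sorbs2 (3.90), Tnc (3.79) and the B cell linker gene Blnk (3.68) rose most. Perp (-4.28, SE 0.26, adjusted p = 0.00454), Ankrd1 (-4.03, SE 0.13, adjusted p = 0.00349), Cyp4f39 (-3.50), Zc3hav1 (-3.47) and Gnal (-3.36) fell most. Lgr5 was higher by 2.65, L1cam by 2.61, Id2 by 1.93 and Sox9 by 1.51, and Ccnd1 (-2.99), C3 (-2.92), Eya1 (-2.85) and Thy1 (-2.77) fell. In all, 706 probe sets were called, 413 higher and 293 lower, and 387 differed by at least 2-fold. These calls depended on the count of the arrays labelled PAX2+Cre as 2 samples. Counted as 1 sample, those arrays gave 0 calls by limma, a smallest adjusted p of 0.0934 and 1187 probe sets under an unadjusted p of 0.05. The count was 0 without either of them, 402 without vector replicate 1, 380 without vector replicate 2, and 2245 without either PAX2 array.

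Cholesterol synthesis genes were higher as a set on the arrays labelled PAX2+Cre than in vector (adjusted p = 3.17e-06, and adjusted p = 0.872 with an estimated correlation). Of 20 members, 5 were called higher, among them Fdft1 (1.24), Cyp51 (1.21) and Fdps (1.10), 0 were lower, and 10 were higher when adjusted over the list alone. Of 30 cell cycle genes, Gins2 (0.98) was called, all 30 lay above 0 and the set was higher (adjusted p = 0.00029, and adjusted p = 0.872 with an estimated correlation). Of 31 replication histone genes, 0 were called over all genes and 7 were higher adjusted over the list alone (adjusted p of the set = 0.0116, and adjusted p = 0.872 with an estimated correlation). With chromosome medians removed, the histone mean was 0.187 against 0.289, 1 gene was called higher and the set stayed higher (adjusted p = 0.000471, and adjusted p = 0.485 with an estimated correlation). Of 16 Hox genes, Hoxc12 (-1.87), Hoxb3 (-1.41) and Hoxb5 (-0.98) fell, and the set was lower (adjusted p = 0.019, and adjusted p = 0.854 with an estimated correlation). Leaving out vector replicate 2 ended the calls of the histone set (mean 0.19 against 0.29) and of the Hox set (-0.41 against -0.50), and a level filter at log2 7 that of the Hox set (-0.32). The other 21 lists did not pass by camera. By fry, the hypoxia and glycolysis (adjusted p = 0.034), Wnt pathway (0.034) and TGF-beta and BMP (0.0499) lists passed. None of the lists called by camera passed by fry (adjusted p between 0.0679 and 0.359). With chromosome medians removed, the epithelial junction set was lower (mean -0.69, adjusted p = 0.0255) and the TGF-beta and BMP set higher (mean 0.59, adjusted p = 0.0173), both at adjusted p = 0.511 with an estimated correlation. Chromosomes 16 (median 0.72), 3 (0.47), 18 (-0.33) and 19 (-0.14) were called, of which 16 (adjusted p = 0.0066) and 18 (adjusted p = 0.027) remained with an estimated correlation, and 3 and 19 did not (adjusted p = 0.863 with an estimated correlation for both). Without vector replicate 2 chromosome 19 stood at -0.031, no longer called, chromosome 3 at 0.27, still called, and chromosome 10 was called (0.23), while without vector replicate 1 chromosome 19 stood at -0.27. With no level filter the medians of chromosomes 16, 3, 18 and 19 were 0.22, 0.16, -0.18 and -0.073, all still called. With chromosome medians removed, 442 probe sets were called, 187 higher and 255 lower, so the split turned towards lower calls.

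The differences of the PAX2 line from vector were largely present on the arrays labelled PAX2+Cre. Of the 1017 calls in PAX2 over vector, 1001 had the same sign there, 577 were also called in the same direction and 0 in the opposite direction. Over all probe sets 78.1% had the same sign. Among 100 draws of unchanged groups that shared simulated vector arrays, the mean was 71.6% and the highest value 72.8%. Noise in these draws was independent for each probe set. Their range leaves out shifts shared by many genes and may be too narrow a reference. Itm2a, Casp1, Tnc, Perp and Ankrd1 were among the shared calls. Independent lists of these sizes would share 20.7 higher and 13.8 lower calls, against 333 and 244 observed. Both comparisons use the same vector arrays, and those simulated draws gave a mean correlation of 0.625 across genes and a mean covariance of 0.0285, against 0.844 and 0.281 observed. Genes are not independent replicates. The covariance was 0.238 and 0.242 where the comparisons shared no array. PAX2 over vector had a covariance of -0.0816 with PAX2+Cre over PAX2, against -0.0416 simulated and -0.0455 and 0.00108 with no array shared. The return fraction, the share of the PAX2 over vector difference lost on the arrays labelled PAX2+Cre, had a median of 0.158 over the 1017 calls, with quartiles of -0.0298 and 0.359. It was 0.0815 for Pax2. Gjb2 was the sole gene both called in PAX2 over vector and called back. Without PAX2 replicate 2, 428 calls were called back and the median return fraction was 0.407, where both comparisons rest on PAX2 replicate 1. Without PAX2 replicate 1 that fraction was 0.238, and 0 calls were called back by limma when that array, either vector array or either array labelled PAX2+Cre was left out. The 577 shared calls became 335 without either vector array, 1478 and 945 without PAX2 replicates 1 and 2, and 0 without either array labelled PAX2+Cre. With the arrays labelled PAX2+Cre counted as 1 sample, 0 calls were shared, since none was left in PAX2+Cre over vector.

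**Figure D3:**
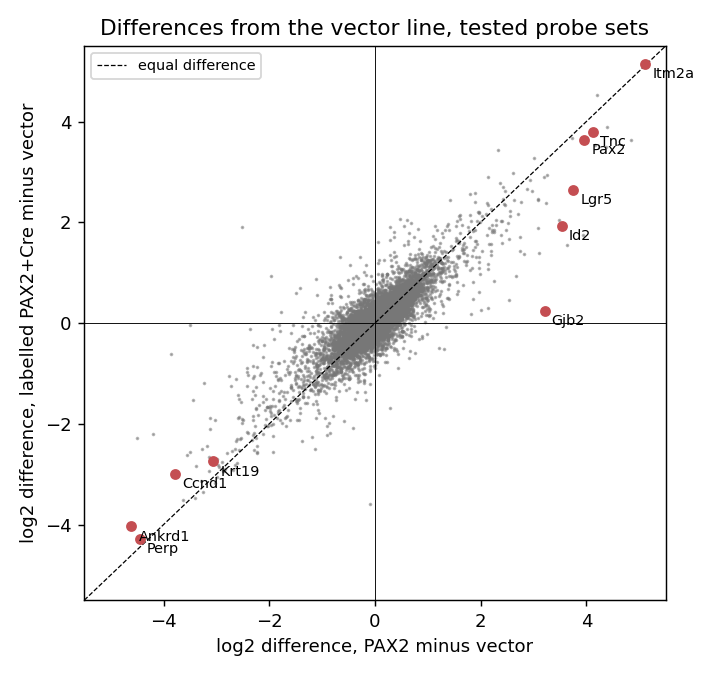
Log2 difference from vector of the arrays labelled PAX2+Cre (vertical axis) against that of the PAX2 arrays (horizontal axis), each grey point a tested probe set, with 10 named genes in red and a dashed line of equal differences. Most named genes lie near the dashed line, as Itm2a does at 5.12 and 5.14, while Gjb2 lies near 0 on the vertical axis.

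The authors' deposited table has a column headed as the ratio of PAX2 to PAX2+Cre. Its log2 values equalled the mean of the arrays labelled PAX2+Cre minus the mean of the vector arrays at every probe set, with a largest deviation of 0, and differed from PAX2 minus PAX2+Cre by up to 7.09. In that column of the authors' deposited table Pax2 stood at 12.4-fold, while PAX2 over PAX2+Cre recomputed from the arrays was 1.25-fold. The column held 884 probe sets at 2-fold or more, and the recomputed difference 238.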

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

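Array weights, chromosome medians removed and the averaged PAX2+Cre arrays were chosen after the data were seen. Call counts for PAX2 over vector, PAX2+Cre over PAX2 and PAX2+Cre over vector, 1017, 1 and 706, stayed within 1.5 times under other level filters, another normalization, median centring, trended variance and averaged probe sets. They moved to 146, 0 and 2245 with only the 2 groups compared, and to 146, 0 and 0 with the arrays labelled PAX2+Cre as 1 sample. Both settings leave fewer samples in the spread estimate and change the part of the close PAX2+Cre pair in it. With only the 2 groups compared, PAX2 over vector, without that pair, fell to 146 calls. PAX2+Cre over vector, with that pair and as few samples, rose to 2245. The counts thus followed which pairs entered the spread estimate, and fewer samples alone do not account for both moves. For PAX2 over vector and PAX2+Cre over vector array weights gave 429 and 2224, and removing chromosome medians gave 442 for the latter, where the cause was not tested. At an adjusted p of 0.1 these counts were 1889 and 1638, at 0.01 they were 136 and 107, and at 2-fold or more 463 and 387. Leaving out each array gave 146 to 1996, 0 to 682 and 0 to 2245 calls, where a lone array is assumed to vary like the other groups.

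The Pax2 difference kept its direction throughout, at 2.96 to 4.95, -0.35 to -0.29 and 2.64 to 4.63 log2 units without each array. Its call in PAX2 over vector ended with only the 2 groups compared and with the averaged arrays (3.96 in both, adjusted p = 0.0794, over a range of 0.00972 to 0.0794), and without PAX2 replicate 1 (3.93, adjusted p = 0.054), PAX2 replicate 2 (3.98, adjusted p = 0.0589) or either array labelled PAX2+Cre (adjusted p = 0.0794). That in PAX2+Cre over vector ended with the averaged arrays (3.63, adjusted p = 0.241) and without chromosome medians (3.79, adjusted p = 0.0524, over a range of 0.00292 to 0.243), and without PAX2+Cre replicate 1 (adjusted p = 0.243) or 2 (adjusted p = 0.236). The 577 calls shared by PAX2 over vector and PAX2+Cre over vector became 142 with only the 2 groups compared, 0 with the averaged arrays, 366 without chromosome medians and 0 to 1478 without each array. The 1 probe set called back became 0 with only the 2 groups compared and 0 with the averaged arrays, and 0 to 428 without each array. The median return fraction stayed between 0.112 and 0.407 without each array.

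With an estimated correlation 0 lists were called in PAX2 over vector, 0 in PAX2+Cre over PAX2 and 0 in PAX2+Cre over vector, and 2, 0 and 2 chromosomes. Without each array 2 to 9, 2 to 5 and 2 to 8 lists and 4 to 5, 0 to 1 and 4 to 4 chromosomes were called. In PAX2 over vector the epithelial junction, TGF-beta and BMP, and hypoxia and glycolysis lists passed by fry. The other lists called there by camera did not (fry adjusted p between 0.16 and 0.435). Of the genes named, Rpl24 in PAX2 over vector changed sign, to -0.12 without chromosome medians, as its chromosome 16 median was removed. Replicate numbers gave deviation correlations of 0.199 for vector with PAX2, 0.0468 for vector with PAX2+Cre and 0.04 for PAX2 with PAX2+Cre. ATF4 and unfolded protein response genes were lower on replicate 1 in both PAX2 and vector (medians -0.60 and -0.48). NRF2 and glutathione genes went opposite ways (-0.44 and 0.38). Whether samples of the same number share more than the number is thus open. The replicate block gave 819 calls in PAX2 over vector, 1 in PAX2+Cre over PAX2, and 301 higher and 204 lower in PAX2+Cre over vector. Term enrichment was not run. Signal against background was not given for these arrays.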

Other observations

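Gene groups also differed between the 2 arrays of a group, described here by medians and by their percentile among 10000 random lists of the same size and level. All 30 cell cycle genes were lower on PAX2 replicate 1 than on PAX2 replicate 2, by a median of -0.92 (percentile 0). On PAX2 replicate 1 angiogenesis genes (-0.54, percentile 0), ATF4 and unfolded protein response genes (-0.60, percentile 0) and immediate early genes (-0.50, percentile 0) were also lower, and 34 of 40 ribosomal protein genes were higher (0.13, percentile 99.8). Between the vector arrays, 0 of 11 interferon response genes were higher on replicate 1 (median -0.91, percentile 0), while 16 of 20 NRF2 and glutathione genes were higher there (0.38, percentile 100).

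The tests below were chosen after the results were seen, except that along chromosome 16. Vector arrays also differed from each other by chromosome: medians relative to their mean were 0.16 and -0.16 on chromosome 3, -0.12 and 0.12 on chromosome 10, and -0.11 and 0.11 on chromosome 19.

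Chromosomes 16, 3 and 18 shifted on all 4 arrays that carry a high Pax2 signal, and chromosome 13 on PAX2 replicate 1. A bias tied to signal level is argued against, since the largest median among 10000 sets of genes of matched level from other chromosomes was 0.10, against 0.68 for chromosome 16. A gain or loss of chromosome copies in the cell populations is a candidate explanation: the shift ran along the whole of chromosome 16, where the smallest median of 4 equal groups of neighbouring genes was 0.64, a test that a regional change would have failed. A response to PAX2 is argued against for chromosome 13, whose median differed by -0.49 between PAX2 arrays of like Pax2 signal. For chromosomes 16 and 18 a response to PAX2 cannot be told apart from the history of the line, because the 4 arrays with high Pax2, with a smallest chromosome 16 median of 0.69, all descend from the PAX2 line.

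The arrays labelled PAX2+Cre kept the Pax2 signal of the PAX2 line. An exchange of labels with the PAX2 arrays is argued against, because it would put a low Pax2 signal on an array labelled PAX2, and the lowest signal there exceeded the highest on a vector array by 2.93. Cells in which the construct was not removed and a probe set that does not read the removed transcript cannot be told apart by the return fraction. The Pax2 probe set rose by 3.96 log2 units from vector to PAX2. The second explanation would therefore need Pax2 RNA other than the construct's to rise too, which was not tested. Among 8 combinations of arrays not shared between the comparisons the mean return fraction was 0.156 and the highest 0.193. These used genes called with both PAX2 arrays. Over all tested probe sets, covariances with no array shared gave 0.0847 (-0.00445 to 0.188). Genes that stay changed after PAX2 is lost would give low values too. Such genes, and a tube of the PAX2 line under this label, were not tested and remain open.

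Pax2 was higher on vector replicate 1 (8.36) than on vector replicate 2 (6.37). A mixture of PAX2-expressing cells or their RNA would, at the 9.94% share this implies, raise genes that are higher in PAX2. For the 59 other genes called at 4-fold or more higher in PAX2 the predicted median was 0.58. The observed median was 0.022, and 54 of the 59 lay below their predicted value. Those calls used the vector mean and a spread that includes the gap between the vector arrays. Genes raised on vector replicate 1 therefore tended to be left out. Among the 21 of the 59 at a log2 signal of 6 or more on vector replicate 2, the predicted median was 0.44 and the observed -0.34. Choosing genes by their signal on vector replicate 2 itself lowers that observed value. A mixture is thus not decided by these genes. An extra copy of chromosome 19, which holds Pax2, is argued against by a median difference of -0.22 between the vector arrays. The origin of this difference stays open.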
